A study of Mus musculus with 8 samples.

How the data were processed

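Gene expression was measured by RNA sequencing in 8 libraries of mouse embryonic stem cells of the E14TG2a line, 2 from each of 4 groups: WT, QKO, QT7 and QT7L1. Per the labels, the cells had spent 48 h in medium with 15% serum and LIF, and libraries were made from 250 ng of total RNA with a stranded TruSeq mRNA kit. Groups were taken from the sample titles. The genotype tags of QT7 and QT7L1 name the opposite factor as the one still present, so the names QT7 and QT7L1 follow the titles throughout. The labels give clones A and B for QKO, QT7 and QT7L1 and no clone for WT.

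Per the submitters' processing notes, reads were converted with bcl2fastq 1.8.4, aligned with STAR 2.4.0f1 to the mm10 (GRCm38) build and assigned to genes with HTSeq; the notes also list DESeq2 under version 2.1.8.3. The version of HTSeq, its strand setting and its treatment of reads that map to several places are not given in the sources used here. The deposited files of the single libraries hold integer counts per Ensembl gene. The deposited comparison tables hold the authors' mean normalised signal, log2 fold changes with standard errors on the log2 scale, a test score and the p-value with its adjusted p-value. The authors' tables were used only for comparison with the calls made here.

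The count files held 47729 gene identifiers and none of the summary lines that HTSeq adds. Of these, 47224 were matched to a gene name in the annotation, and a further 456 had a symbol only in the deposited comparison tables. In GENCODE release M21, which gave the coordinates on GRCm38, 47310 were found. In the deposited tables, 27 gene symbols had been turned into dates or numbers and were taken from the annotation instead. Library sizes were 31.57 and 43.36 (WT), 33.58 and 37.79 (QKO), 38.15 and 42.31 (QT7) and 33.2 and 32.6 (QT7L1), each in 1e+06 counts. The 50 most abundant genes held 11.93 to 13.43% of the counts and mitochondrial genes 0.44 to 1.57%.

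Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default settings, which left 16515. Libraries were scaled by TMM, with factors of 0.955 to 1.028, and 1 quasi-likelihood model with a mean per group was fitted to the 8 libraries (robust dispersion, 4 residual degrees of freedom). The 6 pairs of groups were compared with 2-sided F tests, with p-values adjusted by Benjamini-Hochberg within a comparison and called under 0.05. Fold changes are the first group over the second on the log2 scale, and their standard error (SE) was the absolute log2 fold change divided by the square root of F. Levels are library-size-scaled counts (CPM, per 1e+06 counts) with TMM scaling, given as mean and standard deviation (SD). Log2 CPM used a prior count of 2. This prior was not used for the fitted fold changes, which came from the edgeR fit at its default settings. Fitted fold changes of genes with few counts depend on those settings, and no fold is printed where both groups were at or under 3 counts per library.

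The comparisons, the alternatives, the 22 gene lists and the rule for naming genes were set before the data were examined, apart from the exceptions given here. Lists covered TCF/LEF factors, Wnt/beta-catenin targets, naive and general pluripotency, formative and primed epiblast, primitive streak and mesendoderm, mesoderm, primitive and visceral endoderm, neuroectoderm, trophoblast, 2-cell-like genes, germline, imprinted, LIF/STAT3 targets, BMP and Nodal/Activin targets, p53 targets, glycolysis and hypoxia response, immediate early, histone and cell cycle, Hox, fibroblast (feeder) markers and Y-linked genes. Some genes sit on several lists (Lefty1, Lefty2 and Nodal on the streak and BMP/Nodal lists, T and Wnt3 on the streak and Wnt lists, Gbx2, Klf4 and Tfcp2l1 on the naive and LIF lists). Lists were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison; camera with the correlation estimated from the residuals and fry were run beside it.

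Genes are named by rule. Tcf7, Tcf7l1, Tcf7l2, Lef1 and Axin2 are always given. In each comparison up to 6 higher and 6 lower genes (5 and 5 for a rescued line against WT) are named, those with the largest fold among the called genes with an average log2 CPM of at least 2, no overlap between the libraries compared and a symbol that is not a predicted or clone name. From a list that camera called, or with 3 or more called members, up to 4 members with the smallest adjusted p could be named; the text draws its examples from these. Some genes that the rule selects are not reported here.

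A gene was counted as returned toward WT when QKO against WT and the rescued line against QKO were both called in opposite directions. These comparisons share the QKO libraries, so the overlaps expected by chance (product of the counts in each direction divided by the genes tested) are given beside them, and overlaps and covariances of the fold changes are set beside those in 20 simulated sets without group differences. Sharing no libraries, the QKO against WT and QT7 against QT7L1 differences were also correlated across genes.

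Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no low-count filter, a stricter filter of 1 CPM in 4 libraries, fits of the 2 compared groups alone, leaving out each library in turn and a 2-fold minimum (log2 of at least 1). The replicate numbers were also tried as a block; the labels do not say that equal numbers share a day or a batch. After the data had been seen, 2 alternatives were added: leaving out WT replicate 1 and QKO replicate 1 together, which had the highest Col1a1, and repeating the list tests without each library. When a library is left out, its partner is assumed to vary like the other groups. Chromosome medians used genes with an average log2 CPM of at least 4, and agreement of replicates was checked with a chi-square over genes with at least 20 counts.

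The procedure was tested on simulated counts with the depth and spread of these libraries and 100 genes changed by each factor. Of genes changed 2-fold, 51 to 63% were called over the 6 comparisons, and of genes changed 4-fold 81 to 86%. Between 11 and 21 unchanged genes were called in a comparison. Lists of 18 genes shifted 1.5-fold were found in 20 of 20 sets. Each simulated gene was drawn independently of the others. These rates therefore do not cover lists whose members vary together, and may not hold for the real comparisons. Glycolysis and hypoxia genes, for example, had an estimated inter-gene correlation of 0.582 in QKO against WT.

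Gene counts do not show where in a gene the reads fall, so no exon or isoform of the targeted genes was measured, and protein levels were not analysed here. No grouping of samples by chance splits was run, as groups of 2 libraries allow too few splits.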

Results

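RNA was sequenced from 4 groups of mouse embryonic stem cells, each with n = 2 libraries: WT cells, QKO cells that lack every full-length TCF/LEF factor, and lines in which a single copy of TCF7 (QT7) or TCF7L1 (QT7L1) was put back, as titled. Libraries held 31.57 to 43.36 in units of 1e+06 counts, and 16515 genes were tested. Replicates of a group correlated at r = 0.9901 (WT), 0.9903 (QKO), 0.9815 (QT7) and 0.9912 (QT7L1) in log2 CPM, and differed by more than counting noise (chi-square per degree of freedom 22.57, 18.66, 57.6 and 21.98). On the first principal component (42.3% of the variance) QKO libraries lay at 61.25 and 66.94 and the other 6 libraries between -34.66 and -0.71. On the second (22.7%) QT7 replicate 1 lay at -59.58 and QT7 replicate 2 at -18.89, against 42.22 and 25.37 in WT. Fibroblast markers, which can come from feeder cells, differed between replicates: their mean over 15 genes, centred per gene, was 1.31 and 0.51 in WT, 1.66 and -0.16 in QKO, -1.82 and 0.25 in QT7 and -1.40 and -0.34 in QT7L1. Col1a1 ranged from 51.0 CPM in QKO replicate 1 and 38.6 CPM in WT replicate 1 to 2.58 CPM in QT7 replicate 1. P-values rest on a spread per gene that was estimated from the 4 groups together, and not from the compared groups alone. Replicates are clones A and B in QKO, QT7 and QT7L1, while no clone is given for WT.

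Transcripts of the targeted genes remained countable in every library. Tcf7 (chromosome 11, 52252371 to 52283014 on GRCm38) was at 59.6 and 61.9 CPM in WT, 7.97 and 19.7 in QKO, 16.6 and 20.9 in QT7 and 10.1 and 12.7 in QT7L1. Tcf7l1 (chromosome 6, 72626378 to 72789254) was at 73.6 and 68.8 CPM in WT, 38.3 and 39.1 in QKO, 27.4 and 22.4 in QT7 and 36.9 and 27.5 in QT7L1. Tcf7l2 (chromosome 19, 55741820 to 55933654) was at 8.14 and 6.53 CPM in WT, 7.32 and 7.40 in QKO, 5.84 and 5.27 in QT7 and 5.51 and 4.72 in QT7L1. Lef1 (chromosome 3, 131110471 to 131224356) was at 6.57 and 2.4 CPM in WT, 0.900 and 0.804 in QKO, 1.33 and 0.920 in QT7 and 0.212 and 0.213 in QT7L1. Counts over a whole gene do not measure full-length transcript, since they do not show where in the gene reads fall. The genotype tags name TCF7L1 as the factor left in QT7 and TCF7 in QT7L1, opposite to the titles, and these counts do not settle it: between QT7 and QT7L1 the log2 difference was 0.72 ± 0.37 (SE) for Tcf7 (adjusted p = 0.509) and -0.37 ± 0.15 for Tcf7l1 (adjusted p = 0.42).

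**Figure D1:**
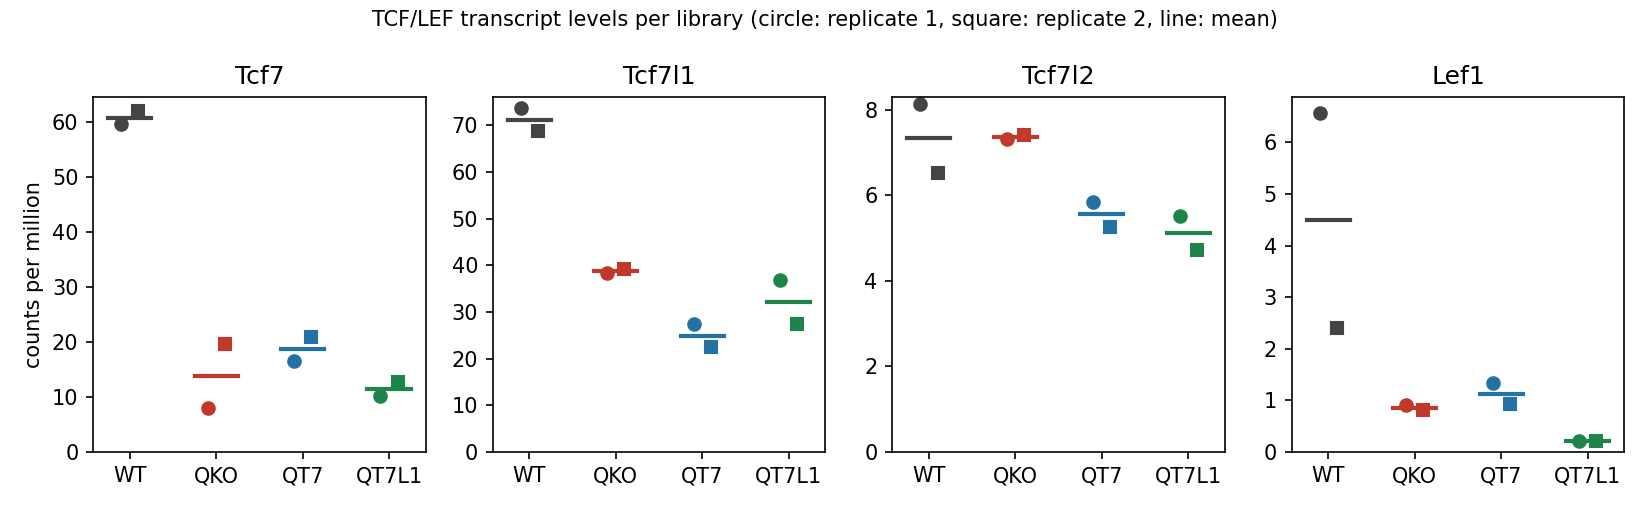
Levels of Tcf7, Tcf7l1, Tcf7l2 and Lef1 in CPM (vertical axes) in each library by group (horizontal axes); circles are replicate 1, squares replicate 2 and lines group means. Tcf7 averaged 60.7 CPM in WT and 13.8, 18.8 and 11.4 CPM in QKO, QT7 and QT7L1.

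QKO differed from WT in 4366 of 16515 genes (26.4%), with 1933 higher and 2433 lower in QKO than in WT (n = 2 each); 419 and 1315 of them differed at least 2-fold. Ndufa4l2, a mitochondrial protein induced by low oxygen, averaged 37.2 ± 8.85 (SD) CPM in WT and 1.74 ± 0.0477 CPM in QKO. Nanog, a core pluripotency factor, rose from 298 ± 14.1 to 595 ± 41.1 CPM, and Lefty1, a secreted inhibitor of Nodal, fell from 127 ± 25.9 to 19.4 ± 3.12 CPM. Axin2, a feedback target of Wnt signalling, rose from 21.3 ± 0.819 to 52.9 ± 10.4 CPM.

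Of the TCF/LEF genes, Tcf7 fell by 2.13 on the log2 scale (SE 0.37, adjusted p = 0.00685), Tcf7l1 by 0.88 (SE 0.15, adjusted p = 0.00381) and Lef1 by 2.39 (SE 0.46, adjusted p = 0.00596), while Tcf7l2 was at 0.01 ± 0.21 (adjusted p = 0.984). The largest rises reported by the naming rule were those of Nt5e (3.15 ± 0.29), an ectonucleotidase, Hal (2.97 ± 0.32), Lrrn2 (2.96 ± 0.26), Ptgs1 (2.69 ± 0.45) and Arl14epl (2.64 ± 0.63). The largest falls were those of Ndufa4l2 (-4.42 ± 0.45), Dppa3 (-3.89 ± 0.67), the mitophagy receptor Bnip3 (-3.48 ± 0.38), the glutamate receptor subunit Grin1 (-3.42 ± 0.36), Got1l1 (-3.41 ± 0.38) and Hapln4 (-3.23 ± 0.47). Axin2 rose by 1.31 ± 0.24 (adjusted p = 0.00617). In the authors' deposited table, a total of 3758 genes had an adjusted p under 0.05, of which 3597 were called here, each in the same direction.

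The number of genes called in QKO depended on single libraries: it was 1310 without WT replicate 2, 2188 without QKO replicate 1 and 1336 without QKO replicate 2. Lef1 (adjusted p = 0.0599 without QKO replicate 2), Axin2 (0.0623 without WT replicate 2), Ptgs1 (0.0733 without WT replicate 2) and Dppa3 (0.0543 and 0.0529 without QKO replicate 1 and 2) lost their calls. Arl14epl lost its call without WT replicate 1 (0.141), WT replicate 2 (0.196), QKO replicate 1 (0.098) or QKO replicate 2 (0.104).

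**Figure D2:**
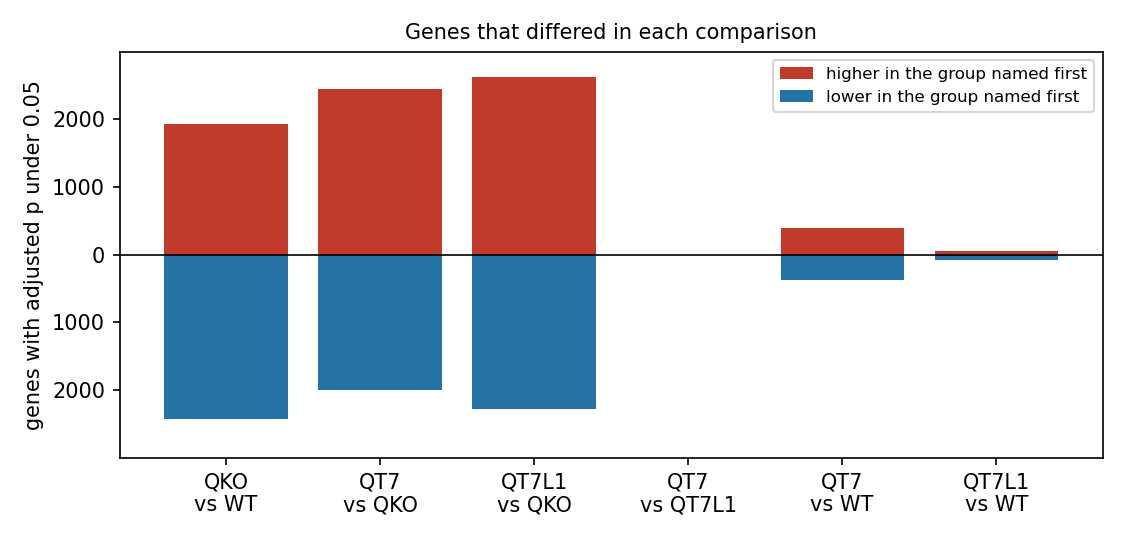
Number of genes called higher and lower (bars, vertical axis) in each of the 6 comparisons (horizontal axis) with edgeR at an adjusted p under 0.05. QT7L1 against QKO gave 2623 higher and 2289 lower genes, and QT7 against QT7L1 gave 1 gene.

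Genes of glycolysis and the hypoxia response were lower in QKO: 17 of 20 fell and 3 did not pass, and 18 were lower when adjusted over the list alone. The glucose transporter Slc2a3 (-1.15 ± 0.11), the oxygen sensor Egln1 (-1.69 ± 0.18), the prolyl hydroxylase P4ha1 (-1.47 ± 0.17) and the glycolytic enzyme Pgk1 (-1.32 ± 0.17) fell. The list's median was -1.13 and camera gave adjusted p = 4.99e-17, against adjusted p = 0.299 with an estimated correlation. Of 16 p53 targets, 11 fell and 5 did not pass (12 lower adjusted over the list alone), with a median of -0.67. Trp53inp1 (-1.16 ± 0.11), Zmat3 (-0.85 ± 0.11), Plk2 (-0.89 ± 0.12) and Trp53cor1 (-2.52 ± 0.42) were among them. Camera gave adjusted p = 4.76e-08 and adjusted p = 0.299 with an estimated correlation. In each of 18 of the 20 hypoxia genes and 12 of the 16 p53 targets both QKO libraries lay below all 6 others. Fibroblast markers did not follow this order, as their mean was highest in QKO replicate 1 (1.66) and lower in QKO replicate 2 (-0.16) than in WT.

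**Figure D3:**
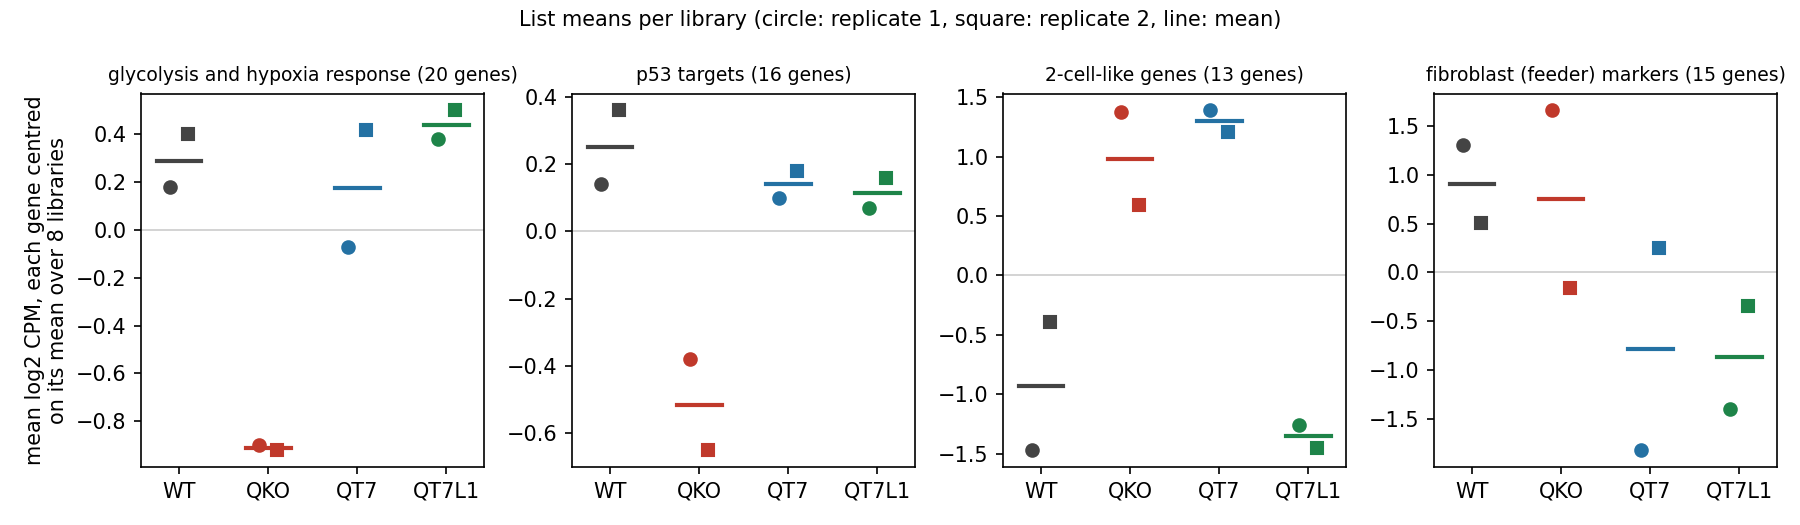
Mean log2 CPM of 4 gene lists in each library (vertical axes, each gene centred on its mean over the 8 libraries) by group (horizontal axes); circles are replicate 1 and squares replicate 2. Glycolysis and hypoxia genes lay at -0.90 and -0.92 in QKO and between -0.07 and 0.50 in the other libraries.

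More of the pluripotency genes rose than fell in QKO. On the naive list 8 of 18 rose, 1 fell and 9 did not pass (10 higher and 2 lower adjusted over the list alone); Nanog (1.00 ± 0.10), Tbx3 (1.04 ± 0.14) and Nr5a2 (0.97 ± 0.13) rose and the maternal factor Dppa3 fell. Their median was 0.39, and camera gave adjusted p = 0.000504, against adjusted p = 0.299 with an estimated correlation. On the general list 6 of 14 rose, 2 fell and 6 did not pass (7 and 2 adjusted over the list alone), with Dppa2 at 0.82 ± 0.11. The camera test gave adjusted p = 0.0154 and adjusted p = 0.299 with an estimated correlation. Of 13 genes of the 2-cell-like state, 7 rose and 6 did not pass (12 higher adjusted over the list alone); Usp17le, a deubiquitinase with near-identical copies, rose by 2.19 ± 0.45. The list's median was 2.12, with adjusted p = 1.94e-05 by camera and adjusted p = 0.299 with an estimated correlation. Of 18 germline genes 5 rose, 1 fell and 12 did not pass (7 and 1 adjusted over the list alone), with Tex19.1 at 1.20 ± 0.14 and Sycp3 at -1.42 ± 0.25. By camera this list had adjusted p = 0.00543 and adjusted p = 0.657 with an estimated correlation. Of 18 cell cycle genes 4 rose, 1 fell and 13 did not pass (4 and 1 adjusted over the list alone), with a median of 0.18. Tested with camera, the list had adjusted p = 0.0439 and adjusted p = 0.657 with an estimated correlation. The germline call ended without WT replicate 1 (adjusted p = 0.101), and the cell cycle call without WT replicate 1 (0.1), QKO replicate 2 (0.127), QT7 replicate 1 (0.0503) or QT7L1 replicate 1 (0.0524). Dppa3 did not pass without QKO replicate 1 (0.0543) or QKO replicate 2 (0.0529).

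The TCF/LEF list itself was lower in QKO (3 of 4 fell and 1 did not pass, 3 lower adjusted over the list alone; camera adjusted p = 0.0123, and adjusted p = 0.299 with an estimated correlation). Without WT replicate 1 camera gave adjusted p = 0.0671. Genes that Wnt/beta-catenin signalling activates went both ways: of 23, 5 rose, 7 fell and 11 did not pass (6 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.901). Their median was 0.05 and their mean -0.13. Per library, the list mean of centred log2 CPM was 0.40 and -0.06 in WT and -0.01 and 0.18 in QKO. WT replicate 1 thus lay above both QKO libraries and WT replicate 2 below both. The cyclin Ccnd1 (0.79 ± 0.13) rose, and the receptor Fzd7 (-0.82 ± 0.09), the antagonist Nkd2 (-2.19 ± 0.31) and Kremen1 (-0.77 ± 0.13) fell. Of 14 BMP and Nodal/Activin targets 2 rose, 2 fell and 10 did not pass (5 and 6 adjusted over the list alone; camera adjusted p = 0.44), with the BMP target Id3 at 2.15 ± 0.16, Skil at -1.36 ± 0.15 and Lefty1 at -2.71 ± 0.16. Of 14 LIF/STAT3 targets 1 rose, 4 fell and 9 did not pass (1 and 4 adjusted over the list alone; camera adjusted p = 0.44), among them the LIF receptor Lifr (-0.58 ± 0.11) and Ier3 (-1.42 ± 0.26). Immediate early genes gave 2 higher, 2 lower and 9 of 13 not passing (2 and 3 adjusted over the list alone; camera adjusted p = 0.827), with Jun at -1.02 ± 0.19 and Klf6 at -0.82 ± 0.15.

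Lineage lists were not called by camera in QKO against WT. Of 18 formative and primed epiblast genes 3 rose, 5 fell and 10 did not pass (3 and 6 adjusted over the list alone; camera adjusted p = 0.381), with Foxd3 at 1.83 ± 0.29 and Car14 at -2.08 ± 0.35. Of 14 primitive streak genes 2 rose, 3 fell and 9 did not pass (4 and 5 adjusted over the list alone; 0.529), including Fgf17 (0.87 ± 0.13) and Lefty1. The 14 mesoderm genes did not pass, also when adjusted over the list alone (0.887), with a median of 0.03 and a mean of -0.18. Of 21 endoderm genes 1 rose, 3 fell and 17 did not pass (1 and 3 adjusted over the list alone; 0.299), with the matrix glycoprotein Sparc at 1.51 ± 0.15, Apoe at -0.96 ± 0.16 and Lamb1 at -0.92 ± 0.17. Of 14 neuroectoderm genes 3 fell and 11 did not pass (3 lower adjusted over the list alone; 0.616). Of 16 trophoblast genes 3 rose, 4 fell and 9 did not pass (6 and 7 adjusted over the list alone; 0.738). Of 25 imprinted genes 2 rose, 3 fell and 20 did not pass (2 and 3 adjusted over the list alone; 0.299), with Dio3 at 2.11 ± 0.33, Sgce at -1.38 ± 0.25 and Peg3 at -0.82 ± 0.15. Hox genes gave 1 higher and 7 of 8 not passing (1 higher adjusted over the list alone; 0.366); Hoxa13, named after its values were seen, rose by 3.03 but lay at 0.448 ± 0.151 CPM in QKO. Fibroblast markers gave 2 higher, 1 lower and 12 of 15 not passing (2 and 1 adjusted over the list alone; 0.844), with Vim at 0.96 ± 0.15, Thy1 at 1.02 ± 0.20 and Fn1 at -0.88 ± 0.14. The 4 Y-linked genes did not pass, also when adjusted over the list alone (median -1.21; camera adjusted p = 0.44).

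QT7, with TCF7 put back as titled, differed from QKO in 4449 genes (26.9%; n = 2 each), with 2451 higher and 1998 lower, of which 1258 and 315 differed at least 2-fold. Ndufa4l2 averaged 1.74 ± 0.0477 (SD) CPM in QKO and 45.7 ± 23.2 CPM in QT7, Bnip3 11.8 ± 2.97 and 113 ± 50.2 CPM, and Lefty1 19.4 ± 3.12 and 56.4 ± 2.28 CPM. The largest rises were those of Ndufa4l2 (4.71 ± 0.46), Grin1 (3.56 ± 0.36), Got1l1 (3.45 ± 0.38), the protease inhibitor A2m (3.44 ± 0.27), the glycogen phosphorylase Pygl (3.32 ± 0.50) and Bnip3 (3.27 ± 0.38). The largest falls were those of Fgfbp1 (-2.36 ± 0.46), Lemd1 (-2.10 ± 0.59), the neural filament gene Nes (-1.85 ± 0.42) and Pou4f2 (-1.81 ± 0.43). Axin2 fell by 1.00 (SE 0.24, adjusted p = 0.0166) and Tcf7l1 by 0.64 (SE 0.15, adjusted p = 0.0137); Tcf7 (0.44 ± 0.36, adjusted p = 0.41), Tcf7l2 (-0.41 ± 0.21, 0.173) and Lef1 (0.40 ± 0.47, 0.573) did not pass. The authors' deposited table had 4021 genes at an adjusted p under 0.05, 3794 of them called here.

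The count in QT7 against QKO was 2346 without QKO replicate 1 and 1478 without QKO replicate 2. Calls ended for Axin2 without QKO replicate 2 (adjusted p = 0.112), for Tcf7l1 without QKO replicate 1 (0.0571), QKO replicate 2 (0.0777) or QT7 replicate 2 (0.0511), and for Fgfbp1 without QT7 replicate 1 (0.0653). They also ended for Pou4f2 without QKO replicate 2 (0.105) and for Nes without QKO replicate 2 (0.0833) or either QT7 library (0.14 and 0.111). Lemd1 lost its call without WT replicate 2, QKO replicate 2, QT7 replicate 1 or either QT7L1 library (0.0508 to 0.179).

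Hypoxia and p53 genes, which were lower in QKO, were higher in QT7 than in QKO. Of 20 glycolysis and hypoxia genes 15 rose and 5 did not pass (16 higher adjusted over the list alone), with P4ha1 at 1.65 ± 0.17, Egln1 at 1.59 ± 0.18, Pgk1 at 1.15 ± 0.16 and Slc2a3 at 1.06 ± 0.11. The list had, by camera, adjusted p = 4.27e-13 at a median of 1.07, and adjusted p = 0.571 with an estimated correlation. Of 16 p53 targets 12 rose and 4 did not pass (12 higher and 1 lower adjusted over the list alone), with Trp53inp1 at 1.23 ± 0.11, Zmat3 at 0.72 ± 0.11 and Ccng1 at 0.55 ± 0.09. With camera it reached adjusted p = 4.2e-05 and adjusted p = 0.571 with an estimated correlation. General pluripotency genes gave 2 higher, 8 lower and 4 not passing (2 and 9 adjusted over the list alone), with the RNA-binding factor Lin28a at -0.93 ± 0.11, Sall4 at -0.72 ± 0.11 and Trim71 at -0.59 ± 0.09. Cell cycle genes gave 1 higher, 9 lower and 8 not passing (1 and 10 adjusted over the list alone), with Pcna at -0.78 ± 0.12, Ccne1 at -1.12 ± 0.20 and Mcm5 at -0.45 ± 0.09. For each of these last lists camera gave adjusted p = 0.00209, and adjusted p = 0.571 with an estimated correlation. The other 18 lists were not called (smallest adjusted p = 0.175). Among them, 5 Wnt targets rose, 4 fell and 14 did not pass (5 and 6 adjusted over the list alone; adjusted p = 0.668), with Ccnd1 at -0.89 ± 0.13 and Kremen1 at 0.74 ± 0.13. Of the 2-cell-like genes 1 fell and 12 did not pass (median 0.40; adjusted p = 0.851), the gene that fell being Eif1a (-0.36), named after its values were seen. Fibroblast markers had a median of -1.84 (2 higher, 13 not passing; adjusted p = 0.385).

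QT7L1, with TCF7L1 put back as titled, differed from QKO in 4912 genes (29.7%; n = 2 each), with 2623 higher and 2289 lower, of which 1271 and 635 differed at least 2-fold. Ndufa4l2 averaged 55.7 ± 15.0 (SD) CPM in QT7L1, Bnip3 145 ± 38.1 CPM and Nanog 443 ± 3.41 CPM, against 1.74 ± 0.0477, 11.8 ± 2.97 and 595 ± 41.1 CPM in QKO. The largest rises were those of Ndufa4l2 (5.0 ± 0.46), Pygl (3.81 ± 0.51), Bnip3 (3.63 ± 0.39), Ccng2 (3.52 ± 0.22), the oxygen-sensing hydroxylase Egln3 (3.41 ± 0.36) and Grin1 (3.31 ± 0.36). The largest falls were those of Zscan4d (-3.66 ± 0.76), Serpinb9b (-2.72 ± 0.46), Nlrc4 (-2.67 ± 0.81), the protease Klk10 (-2.50 ± 0.37) and the egg-coat gene Zp3 (-2.32 ± 0.28). Lef1 fell by 1.98 (SE 0.58, adjusted p = 0.0286) and Axin2 by 0.73 (SE 0.24, adjusted p = 0.0482). Tcf7 (-0.29 ± 0.37, adjusted p = 0.594), Tcf7l1 (-0.26 ± 0.15, 0.217) and Tcf7l2 (-0.52 ± 0.21, 0.0837) did not pass. The authors' deposited table had 4217 genes at an adjusted p under 0.05, 4101 of them called here.

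The count in QT7L1 against QKO was 2884 without QKO replicate 1, 1773 without QKO replicate 2, 2378 without QT7L1 replicate 1 and 1974 without QT7L1 replicate 2. Lef1 lost its call without QKO replicate 1 (adjusted p = 0.0979), QKO replicate 2 (0.0927), QT7L1 replicate 1 (0.129) or QT7L1 replicate 2 (0.133), and Axin2 without any of the WT, QKO or QT7L1 libraries (0.0554 to 0.262). Zscan4d lost it without either QT7L1 library (0.0647 and 0.0898), and Nlrc4 without either QKO or either QT7L1 library (0.0577 to 0.201).

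In QT7L1, 18 of 20 glycolysis and hypoxia genes rose against QKO and 2 did not pass (18 higher adjusted over the list alone), with Egln1 at 1.89 ± 0.18, P4ha1 at 1.68 ± 0.17, Pgk1 at 1.49 ± 0.17 and Slc2a3 at 1.14 ± 0.11. Camera gave adjusted p = 2.26e-19 for their median of 1.20, and adjusted p = 0.474 with an estimated correlation. Of 16 p53 targets 10 rose and 6 did not pass (11 higher adjusted over the list alone), with Trp53inp1 at 1.08 ± 0.11, Bbc3 at 1.59 ± 0.26 and Phlda3 at 0.75 ± 0.14. The camera test gave adjusted p = 9.38e-05 and adjusted p = 0.649 with an estimated correlation. General pluripotency genes gave 2 higher, 7 lower and 5 not passing (3 and 9 adjusted over the list alone), with Dppa2 at -0.95 ± 0.11, Lin28a at -0.85 ± 0.11 and L1td1 at -0.73 ± 0.11. By camera this list had adjusted p = 0.00366 and adjusted p = 0.474 with an estimated correlation. The 2-cell-like genes fell: 11 of 13 were lower and 2 did not pass (13 lower adjusted over the list alone), with Zfp352 at -4.31 ± 0.81 and Usp17le at -2.57 ± 0.47. Their median was -2.64, with adjusted p = 1.43e-06 by camera and adjusted p = 0.474 with an estimated correlation. The other 18 lists were not called (smallest adjusted p = 0.285). Among them, 6 Wnt targets rose, 7 fell and 10 did not pass (6 and 9 adjusted over the list alone; adjusted p = 0.463), with Fzd7 at 0.72 ± 0.09, Nkd2 at 1.85 ± 0.31 and Ccnd1 at -0.90 ± 0.13. Naive genes gave 3 higher, 6 lower and 9 not passing (adjusted p = 0.309), with Tcl1 at 0.72 ± 0.12 and Nr5a2 at -0.74 ± 0.13. Fibroblast markers had a median of -2.30 (2 higher, 1 lower, 12 not passing; adjusted p = 0.285).

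Of the 4366 genes that differed between QKO and WT, 2656 (60.8%) moved back toward WT in QT7, 1505 that had fallen and 1151 that had risen. In QT7L1 3102 (71%) did, 1721 and 1381. Chance overlap would give 361.1 and 233.9 genes in QT7 and 386.4 and 267.9 in QT7L1, which leaves out the sharing of QKO libraries. In 20 simulated sets that share them but hold no group differences the overlap was at most 1, which leaves out real effects. Both lines returned 2372 genes (54.3%), among them Ndufa4l2, Bnip3, Slc2a3 and Trp53inp1; 284 returned in QT7 alone, 730 in QT7L1 alone and 980 (22.4%) in neither. These groupings rest on separate thresholds and were not tested against each other. A gene in which only the QKO libraries stand apart counts as returned in both lines. The counts therefore do not separate an effect of the factors from a culture state particular to the QKO libraries. The covariance of the QKO against WT and QT7 against QKO differences was -0.411 (simulated -0.07, difference -0.341), and with QT7L1 against QKO -0.551 (simulated -0.0698, difference -0.482). The rescued lines changed 3298 genes in the same direction against QKO, where 666.2 would be expected (covariance 0.517, simulated 0.0699, difference 0.447). Part of the excess in these overlaps may come from the shared QKO libraries, as 2 control libraries are too few to divide between the comparisons. Returned genes numbered 834 (QT7) and 979 (QT7L1) without WT replicate 2, 1287 and 1557 without QKO replicate 1, and 676 and 834 without QKO replicate 2. In QT7L1 they numbered 1742 without QT7L1 replicate 1 and 1481 without QT7L1 replicate 2.

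Between the rescued lines, 1 gene passed with edgeR. It was Gm47283, annotated on chromosome Y (-1.01 ± 0.11, adjusted p = 0.0467, named after its values were seen). With edgeR 1830 genes had an unadjusted p under 0.05, while DESeq2 called 235 (206 higher and 29 lower in QT7) and limma-voom 0. The authors' deposited table had 214 at an adjusted p under 0.05. Directions between these lines follow the titles, which the genotype tags contradict. Lef1 averaged 1.12 ± 0.288 (SD) CPM in QT7 and 0.213 ± 0.000835 CPM in QT7L1 (2.38 ± 0.57 (SE), adjusted p = 0.19; DESeq2 adjusted p = 0.0253); Tcf7l2 was at 0.12 ± 0.21 (0.856) and Axin2 at -0.27 ± 0.24 (0.704). The count of 1 became 17 without either WT library, 3 without QT7 replicate 1, 1396 without QT7 replicate 2, and 0 without QKO replicate 1, QKO replicate 2, QT7L1 replicate 1 or QT7L1 replicate 2. Across 16515 genes the QT7 against QT7L1 difference correlated with the QKO against WT difference at r = 0.296 (covariance 0.14, simulated -0.000199), between libraries that are not shared; genes are not independent replicates.

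Camera called gene lists between QT7 and QT7L1 although none of their members passed with edgeR over all genes. The 13 genes of the 2-cell-like state had a median of 3.14 in QT7 against QT7L1, and 12 were higher when adjusted over the list alone; Eif1a was at 0.05 ± 0.10. Tested with camera, the list had adjusted p = 4.09e-25, and adjusted p = 0.127 with an estimated correlation. With fry it had adjusted p = 0.122. Zfp352 was at 4.59 ± 0.79 (adjusted p = 0.111), Usp17lc at 4.02 ± 0.68 (0.111), Zscan4f at 3.35 ± 0.57 (0.113) and Usp17le at 3.08 ± 0.46 (0.111). Levels in QT7L1 were low, with Zfp352 at 0.0303 and 0.0305 CPM and Usp17lc at 0.182 and 0.0914 CPM. Apart from Eif1a, no member lay above 1.12 CPM there. The authors' deposited table gives Zscan4f at 2.00 (authors' adjusted p = 2.23e-07) and Usp17le at 1.59 (0.000285). Over the tested genes the authors' log2 fold changes had a slope of 0.4 on those fitted here, so the sizes are not on the same scale. Without each library in turn the camera value for this list lay between 5.48e-36 and 6.75e-13. Germline genes had a median of 0.60 (5 higher and 1 lower adjusted over the list alone), with Tex19.1 at 0.69 ± 0.14 (0.16). The list had, by camera, adjusted p = 0.000271 and adjusted p = 0.653 with an estimated correlation. Endoderm genes had a median of 0.62 (1 higher adjusted over the list alone), with Hnf4a at 1.33 ± 0.32 (0.207), and glycolysis and hypoxia genes a median of -0.26 (no member adjusted over the list alone), with Pgk1 at -0.34 ± 0.16 (0.478). For each, camera gave adjusted p = 0.000151 and adjusted p = 0.653 with an estimated correlation. Cell cycle genes had a median of -0.15 (camera adjusted p = 0.00653) and Hox genes of 0.82 (camera adjusted p = 0.0419), with no member passing when adjusted over the list alone and, for each, adjusted p = 0.653 with an estimated correlation. Without QT7 replicate 1 camera gave adjusted p = 0.0786 for endoderm, 0.58 for hypoxia, 0.0786 for cell cycle and 0.58 for Hox genes. Hox genes were at 0.142 without QT7L1 replicate 2 and germline genes at 0.0577 without QT7L1 replicate 1.

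QT7 differed from WT in 763 genes (4.6%; n = 2 each), 391 higher and 372 lower, 455 of them at least 2-fold. Nanog averaged 544 ± 55.7 (SD) CPM in QT7 and 298 ± 14.1 CPM in WT, and Lefty1 56.4 ± 2.28 and 127 ± 25.9 CPM. Tcf7 (-1.69 ± 0.36, adjusted p = 0.0456), Tcf7l1 (-1.51 ± 0.16, 0.00163) and Lef1 (-1.99 ± 0.45, 0.038) were lower than in WT, while Tcf7l2 (-0.40 ± 0.21, 0.321) and Axin2 (0.32 ± 0.24, 0.525) did not pass. The largest rises were those of Arl14epl (3.49 ± 0.65), Zfp264 (3.01 ± 0.65), Tuba3a (2.85 ± 0.55), Lrrn2 (2.76 ± 0.26) and Ptgs1 (2.64 ± 0.45). The largest falls were those of Dppa3 (-3.32 ± 0.64), Lemd1 (-3.30 ± 0.60), Sema3e (-2.37 ± 0.29), Atp10a (-2.37 ± 0.30) and Miip (-2.22 ± 0.30). The authors' deposited table had 1159 genes at an adjusted p under 0.05, 711 of them called here. The count was 50 without WT replicate 1, 351 without WT replicate 2, 488 and 482 without QKO replicate 1 and 2, 395 and 1914 without QT7 replicate 1 and 2, and 344 and 339 without QT7L1 replicate 1 and 2. Of 39 named genes that passed, 7 (Tcf7l1, Nanog, Lefty1, Id3, Lrrn2, Sema3e and Atp10a) passed without each of the 8 libraries. Tcf7 lost its call without any of the WT, QT7 or QT7L1 libraries (0.081 to 0.249), and Lef1 without any library but WT replicate 2 (0.0617 to 0.3). Arl14epl and Zfp264 lost it without any WT, QKO or QT7L1 library (0.0723 to 0.302), Tuba3a without any library but WT replicate 2 (0.0541 to 0.191) and Dppa3 without any WT, QKO or QT7 library (0.0556 to 0.172). Ptgs1 lost it without WT replicate 1 (0.175), WT replicate 2 (0.136) or QKO replicate 1 (0.0511), Miip without WT replicate 1 (0.059) and Lemd1 without either WT library, QT7 replicate 1 or either QT7L1 library (0.064 to 0.169).

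Against WT, 5 of 13 genes of the 2-cell-like state were higher in QT7 and 8 did not pass (12 higher adjusted over the list alone), with a median of 2.36 and Usp17le at 2.70 ± 0.44. With camera it reached adjusted p = 8.47e-11 and adjusted p = 0.181 with an estimated correlation. Germline genes gave 4 higher, 1 lower and 13 not passing (9 and 1 adjusted over the list alone), with Mael at 1.64 ± 0.25. Camera gave adjusted p = 2.51e-06 and adjusted p = 0.304 with an estimated correlation. Naive genes gave 4 higher, 1 lower and 13 not passing (8 and 1 adjusted over the list alone), with Nanog at 0.87 ± 0.10. The camera test gave adjusted p = 0.000476 and adjusted p = 0.254 with an estimated correlation. Formative genes gave 4 lower and 14 not passing (9 lower adjusted over the list alone), with the methyltransferase gene Dnmt3b at -1.04 ± 0.16. By camera this list had adjusted p = 3.03e-05 and adjusted p = 0.181 with an estimated correlation. TCF/LEF genes gave 3 lower and 1 not passing (3 lower adjusted over the list alone). Tested with camera, the list had adjusted p = 8.05e-07 and adjusted p = 0.181 with an estimated correlation. Immediate early genes (2 lower of 13, 4 adjusted over the list alone; camera adjusted p = 0.023, and adjusted p = 0.304 with an estimated correlation) and imprinted genes (1 higher and 4 lower of 25, 1 and 6 adjusted over the list alone; 0.0075, and adjusted p = 0.254 with an estimated correlation) were lower by camera. It also called neuroectoderm genes (lower, median -0.36; 2 lower of 14, 3 adjusted over the list alone; 0.0282, and adjusted p = 0.254 with an estimated correlation) and Hox genes (higher, median 0.68; 8 of 8 not passing, 1 higher adjusted over the list alone; 0.0401, and adjusted p = 0.434 with an estimated correlation). Hox genes were not called without WT replicate 2 (0.102) or QT7 replicate 1 (0.484), imprinted genes without WT replicate 1 (0.0719) or QT7 replicate 2 (0.141), nor neuroectoderm genes without QT7 replicate 2 (0.255). Usp17le (0.0927), Mael (0.0547) and Dnmt3b (0.0756) lost their calls without WT replicate 1. Hypoxia genes had a median of -0.13 (1 lower, 19 not passing; 0.177) and p53 targets of -0.10 (16 not passing; 0.143). Id3, on the BMP and Nodal/Activin list, was at 1.21 ± 0.16 and Lefty1 at -1.17 ± 0.15.

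QT7L1 differed from WT in 123 genes (0.7%; n = 2 each), 49 higher and 74 lower, 70 of them at least 2-fold. Lefty1 averaged 42.6 ± 0.584 (SD) CPM in QT7L1 and 127 ± 25.9 CPM in WT, and Nanog 443 ± 3.41 and 298 ± 14.1 CPM. Tcf7 (-2.42 ± 0.37, adjusted p = 0.0406), Tcf7l1 (-1.14 ± 0.15, 0.0161) and Lef1 (-4.37 ± 0.55, 0.0149) were lower, while Tcf7l2 (-0.52 ± 0.21, 0.273) and Axin2 (0.58 ± 0.24, 0.296) did not pass. The largest rises were those of Hal (1.76 ± 0.31), Nt5e (1.66 ± 0.28), Lrrn2 (1.56 ± 0.26), Slc15a1 (1.51 ± 0.26) and Klk13 (1.39 ± 0.23). The largest falls, beside Tcf7, were those of Sema3e (-2.19 ± 0.29), the ephrin Efnb2 (-2.12 ± 0.34), Cd109 (-1.93 ± 0.35) and the phosphatase Dusp4 (-1.93 ± 0.30). The authors' deposited table had 460 genes at an adjusted p under 0.05, 123 of them called here. The count was 7 without WT replicate 1, 76 without QKO replicate 1, 517 and 499 without QT7 replicate 1 and 2, 2 without QT7L1 replicate 1 and 0 without QT7L1 replicate 2. Each of the 20 named genes that passed lost its call without QT7L1 replicate 1 and without QT7L1 replicate 2, for example Lefty1 (0.0758 and 0.168), Tcf7l1 (0.0738 and 0.185) and Lef1 (0.129 and 0.185). Of the same 20, 19 lost it without WT replicate 1, 11 without WT replicate 2, 8 and 6 without QKO replicate 1 and 2, and 1 without each QT7 library.

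Against WT, TCF/LEF genes gave 3 lower and 1 not passing in QT7L1 (4 lower adjusted over the list alone). The list had, by camera, adjusted p = 1.03e-11 and adjusted p = 0.106 with an estimated correlation. Naive genes gave 3 higher and 15 not passing (9 higher and 2 lower adjusted over the list alone), with Nanog at 0.57 ± 0.10, Tbx3 at 0.87 ± 0.14 and Tfcp2l1 at 0.56 ± 0.10. With camera it reached adjusted p = 0.000314 and adjusted p = 0.232 with an estimated correlation. Formative genes gave 1 lower and 17 not passing (8 lower adjusted over the list alone), with Dnmt3b at -1.05 ± 0.16. Camera gave adjusted p = 2.62e-05 and adjusted p = 0.187 with an estimated correlation. Imprinted genes gave 1 lower and 24 not passing (2 lower adjusted over the list alone), with Peg10 at -1.40 ± 0.21. The camera test gave adjusted p = 9.59e-05 and adjusted p = 0.187 with an estimated correlation. The 4 Y-linked genes did not pass (median -3.59), also when adjusted over the list alone. By camera this list had adjusted p = 0.00631 and adjusted p = 0.376 with an estimated correlation. Camera also called as lower the streak (median -0.62; 1 lower of 14, 1 higher and 2 lower adjusted over the list alone; 0.0156, and adjusted p = 0.187 with an estimated correlation), neuroectoderm (median -0.43; 14 not passing, 2 lower adjusted over the list alone; 0.0131, and adjusted p = 0.187 with an estimated correlation) and endoderm genes (median -0.68; 1 higher of 21, 1 higher and 1 lower adjusted over the list alone; 0.0129, and adjusted p = 0.495 with an estimated correlation). It called germline genes higher (median 0.30; 18 not passing, 1 higher adjusted over the list alone; 0.033, and adjusted p = 0.495 with an estimated correlation). Also called lower were p53 targets (16 not passing, 1 lower adjusted over the list alone, median -0.10; 0.0464, and adjusted p = 0.495 with an estimated correlation), immediate early genes (median -0.26; 1 lower of 13, 4 adjusted over the list alone; 0.0332, and adjusted p = 0.376 with an estimated correlation) and fibroblast markers (15 not passing, median -2.52; 0.0463, and adjusted p = 0.495 with an estimated correlation). Hypoxia genes had a median of 0.16 (20 not passing; 0.0974) and 2-cell-like genes of -0.78 (13 not passing; 0.0995).

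Calls of QT7L1 against WT ended in single-library fits for several lists. Endoderm genes lay at 0.81 without WT replicate 2, with the direction reversed, and at 0.0663 without QT7L1 replicate 2. Fibroblast markers were at 0.166 without WT replicate 1 and 0.16 without QT7L1 replicate 1, and germline genes at 0.475 without WT replicate 1 and 0.41 without QT7L1 replicate 2. The p53 targets were at 0.57 without WT replicate 2, 0.0627 and 0.0606 without QT7 replicate 1 and 2, and 0.16 without QT7L1 replicate 1. Immediate early genes were at 0.058 without WT replicate 1, 0.0565 and 0.057 without QKO replicate 1 and 2, and 0.0923 without QT7L1 replicate 2. Neuroectoderm genes were at 0.0663 and streak genes at 0.0879 without QT7L1 replicate 2.

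Of the genes that differed between QKO and WT, 234 lower and 203 higher genes were still called in the same direction in QT7 against WT and 53 and 36 in QT7L1 against WT, and 85 (34 higher and 51 lower) were called in the same direction in all 3 lines. The WT libraries are shared, so part of this agreement may come from them. The 3 lines are clones and no clone is given for WT, so genotype and clonal origin cannot be told apart here. The QKO and QT7 differences from WT had a covariance of 0.241 (simulated 0.068) and r = 0.455 (simulated 0.5). For QKO and QT7L1 the covariance was 0.101 (simulated 0.0682) and r = 0.22 (simulated 0.491). Nanog was at 1.00, 0.87 and 0.57 in QKO, QT7 and QT7L1, Tbx3 at 1.04, 1.12 and 0.87, and Sparc at 1.51, 1.31 and 0.81. Lefty1 was at -2.71, -1.17 and -1.57, and Dnmt3b at -0.54, -1.04 and -1.05. The comparisons of QT7 and QT7L1 with WT shared 109 genes in direction, where 2.8 would be expected (covariance 0.207, simulated 0.0681); part of the excess in this overlap may come from the shared WT libraries. These groupings move with the counts of the QT7 and QT7L1 comparisons with WT, which were 50 and 7 without WT replicate 1.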

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

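The tests of the explanations in this part were chosen after the results were seen, and the list tests without each library were added after the data had been examined.

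The 2-cell-like genes had a median log2 difference of 3.14 between QT7 and QT7L1, at levels of 1.12 CPM or less in QT7L1 for all but Eif1a. Camera gave adjusted p = 4.09e-25, and adjusted p = 0.127 with an estimated correlation, while fry gave adjusted p = 0.122. None of the 13 members passed over all genes with edgeR. QKO libraries showed them too: for 12 of the 13 members, all but Eif1a, the QKO and QT7 libraries lay above the WT and QT7L1 libraries, although Tcstv3 was at 0.249 CPM to the digits printed in both QKO replicate 2 and WT replicate 2. Reads shared within the Zscan4, Usp17l and Tcstv families were argued against as the whole source by a median of 2.88 over the 6 members outside them. Of these 6, 5 had both QT7 libraries above both QT7L1 libraries. Reads that these 6 may share with copies of their own were not tested. A single aberrant QT7 library was argued against by medians of 3.44 without QT7 replicate 1 and 3.25 without QT7 replicate 2. Replicates differed in these genes also within WT and QKO. The list mean of centred log2 CPM was -1.47 and -0.39 in WT and 1.38 and 0.59 in QKO. In QT7 it was 1.39 and 1.21, and in QT7L1 -1.26 and -1.45. Variation of these genes between cultures or clones was not tested as an explanation. A candidate explanation is that the factor put back in QT7L1 represses these genes and that in QT7 does not; this hypothesis was found in the same data, stays untested and depends on whether titles or genotype tags name the factor.

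Gm47283, annotated on chromosome Y at 90784738 to 90816464, was lower in QT7 than in QT7L1 (-1.01, chosen after its values were seen). It lay at 104 and 89.5 CPM in QT7L1, 47 and 49.3 CPM in QT7 and 70.1 and 67.8 CPM in WT, so QT7L1 was above WT. The Y-linked genes of the list varied between clones, and Uty and Ddx3y lay below WT in QT7L1. The listed Y genes lie far from Gm47283, between 897788 and 1286629. The tests below cover listed genes and not Gm47283. Whether reads of Gm47283 come from chromosome Y or are shared with another chromosome was not tested. Relative to the WT mean, Uty and Ddx3y were at 10.8 and 13.4% in QT7L1 replicate 1, 2.2 and 7.5% in QT7L1 replicate 2, 13.9 and 20.3% in QKO replicate 1 and 8.3 and 25.2% in QT7 replicate 2, whereas Kdm5d, at 13 and 21 counts in WT, had 8 and 2 in QKO, 98 and 5 in QT7 and 0 and 1 in QT7L1, and was left out of the ratios below for its few counts. Reads shared with X-linked copies were argued against by 3 libraries with low Uty and Ddx3y in which the X-linked copies stayed near WT (72.6 to 142.2% over the 6 libraries outside WT). In the QT7L1 libraries loss of the whole chromosome in a share of cells was argued against, since Eif2s3y remained at 57.3 and 109.1% and the largest and smallest share among Eif2s3y, Uty and Ddx3y differed by at least 5.31 times. In QKO replicate 1 and QT7 replicate 2 that ratio was 2.18 and 3.99, so loss of the chromosome in a share of cells and other differences between clones cannot be told apart at 1 library each.

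Camera at its preset correlation also called endoderm genes (median 0.62), germline genes (0.60) and Hox genes (0.82) higher in QT7 than in QT7L1, and glycolysis and hypoxia genes (-0.26) and cell cycle genes (-0.15) lower. Each of these calls was lost with an estimated correlation (adjusted p = 0.653) and with fry (adjusted p = 0.453 to 0.52). No member passed over all genes with edgeR. Without QT7 replicate 1 the endoderm (0.0786), Hox (0.58), hypoxia (0.58) and cell cycle (0.0786) calls ended. The Hox call also ended without QT7L1 replicate 2 (0.142) and the germline call without QT7L1 replicate 1 (0.0577). No explanation was tested for these lists.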

How the results depend on the processing

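No scaling moved the median of all genes by more than 0.06 on the log2 scale. The libraries called feeder-rich here are WT replicate 1 and QKO replicate 1, with the highest fibroblast marker means (1.31 and 1.66). The labels do not mention feeders, and the source of this RNA was not shown. Without both, 1 library each of WT and QKO remains, so a lower count cannot be credited to these markers. In QKO against WT the 4366 genes became 1734 with a 2-fold minimum, 1294 without the 2 libraries with the most feeder marker RNA, and 1310 (without WT replicate 2) to 5493 (without QT7 replicate 1) leaving out 1 library. In QT7 against QKO the 4449 became 1573, 1844, and 1478 (without QKO replicate 2) to 4270 (without QT7 replicate 2). In QT7L1 against QKO the 4912 became 1906, 2384, and 1773 (without QKO replicate 2) to 5982 (without QT7 replicate 2). In QT7 against QT7L1 the single gene became 235 with DESeq2, 0 with limma-voom, 3 with upper-quartile scaling (2 higher and 1 lower), 1030 without the low-count filter, 2 with the stricter filter, 19 with the 2 groups alone, 11 without the feeder-rich libraries, and 0 (without QKO replicate 1) to 1396 (without QT7 replicate 2). In QT7 against WT the 763 became 1300 with DESeq2, 2203 without the filter, 122 with the 2 groups alone, 31 without the feeder-rich libraries, 455 with a 2-fold minimum, and 50 (without WT replicate 1) to 1914 (without QT7 replicate 2). In QT7L1 against WT the 123 became 568, 1248, 655, 7 and 70 in the same order, and 0 (without QT7L1 replicate 2) to 517 (without QT7 replicate 1).

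The 2656 genes returned in QT7 became 819 with a 2-fold minimum, 887 without the feeder-rich libraries, and 676 (without QKO replicate 2) to 2861 (without QT7 replicate 1). The 3102 returned in QT7L1 became 1095, 1058, and 834 (without QKO replicate 2) to 3958 (without QT7 replicate 2). The correlation of 0.296 between the QT7 against QT7L1 and QKO against WT differences was 0.124 without the filter and 0.231 (without QT7 replicate 1) to 0.329 (without WT replicate 2). A 2-fold minimum lowers a count by construction; the cause was not tested for the other shifts. Of 43 list calls, fry kept 17 and camera with an estimated correlation kept 0. None of the lists called between QT7 and QT7L1 was kept by fry (smallest adjusted p = 0.122). Without 1 library at a time the endoderm value in QT7L1 against WT ran from 5.38e-21 (without WT replicate 1) to 0.81 (without WT replicate 2, direction reversed). Of 294 calls of named genes, 290 held with DESeq2, 282 with limma-voom and 162 without the feeder-rich libraries.

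With a replicate block the 6 counts were 4303, 4390, 4853, 2, 801 and 169, and the returned genes 2639 and 3051. The replicate block ended 3 of 43 list calls: cell cycle genes in QKO against WT (adjusted p = 0.0505), and p53 targets (0.0659) and fibroblast markers (0.134) in QT7L1 against WT. It ended 11 of 294 calls of named genes, among them Lemd1 in QT7 against QKO (0.0834) and against WT (0.0768), Nlrc4 in QT7L1 against QKO (0.0679), and Zfp264 (0.103) and Tuba3a (0.122) in QT7 against WT. Correlations between groups of the difference between replicate 1 and replicate 2 ran from -0.21 (QKO with QT7) to 0.16 (QT7 with QT7L1), so the numbers were not treated as pairs.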

Other observations

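The tests of the explanations in this part were chosen after the results were seen. The fit without WT replicate 1 and QKO replicate 1, the libraries highest in fibroblast markers, was added after the data had been examined.

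Glycolysis and hypoxia genes were lower in QKO than in WT (camera adjusted p = 4.99e-17, and adjusted p = 0.299 with an estimated correlation), and for 18 of 20 genes both QKO libraries lay below all 6 others. The choice among the scalings tried did not account for the fall, since the median was -1.13 with TMM, -1.12 with RLE and -1.15 with upper-quartile scaling. The median of all genes was -0.005, 0.007 and -0.026 in the same order. These scalings thus differed too little to test scaling more widely. Feeder RNA was argued against: QKO replicate 1 lay 1.08 below WT replicate 1, the library nearest to it in fibroblast markers (1.66 and 1.31), and QKO replicate 2 lay 1.42 below QT7L1 replicate 2 (-0.16 and -0.34), while replicates of a group differed by at most 0.49. The smallest gap between QKO and another group was 2.23 times the largest difference between replicates, but the labels give neither density nor oxygen at harvest, so a difference in culture state and an effect of the genotype cannot be told apart. That TCF/LEF loss itself may lower these genes stays an untested hypothesis.

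The germline list had a mean of 0.72 in QT7 replicate 1 and 0.16 in replicate 2, a difference that was not tested. Of single genes chosen after their values were seen, Sohlh2 was at 98.2 and 36.6 CPM, Dazl at 30.9 and 11.1 CPM and Hormad1 at 22.3 and 6.3 CPM. WT replicate 1 had T at 9.70 CPM and Fgf5 at 3.6 CPM, against 0.680 and 0.385 CPM in WT replicate 2. The median of 352 genes of chromosome 6, each centred over the 8 libraries, was 0.023 and 0.116 in WT, 0.048 and 0.057 in QKO, -0.060 and -0.072 in QT7 and -0.060 and -0.064 in QT7L1. It lay above the range of 1000 random gene sets in both WT libraries, below it in the QT7 and QT7L1 libraries and within it in QKO. In WT replicate 2 it was 0.147 above the all-chromosome value, the largest such shift among autosomes and X; the next was -0.076, for chromosome 18 in QT7L1 replicate 1 (chromosome Y had 3 genes and was not ranked). Some medians of other chromosomes lay outside their random ranges as well. Against WT the chromosome 6 median was -0.133 in QT7 and -0.129 in QT7L1, the furthest from 0 among autosomes in these comparisons, and no explanation was tested. The 2 lines with a factor put back kept lower Lefty1 than WT (-1.17 and -1.57) and higher Nanog (0.87 and 0.57).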
